A study of Homo sapiens with 18 samples.

How the data were processed

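Gene expression was measured by RNA sequencing in 18 libraries of the human colorectal cancer lines HT-29 iZEB1 (12 libraries) and SW620 (6 libraries). Per the labels' protocols, cells were grown in 6-well plates, RNA was extracted with a commercial kit and treated with DNase, mRNA was purified, and libraries were sequenced on a BGISEQ-500. The deposited table holds whole-number counts of reads per gene, not normalised, for 60642 gene symbols in 18 columns, 1 for each library. Per the submitters' processing notes the tools were FastQC 0.11.9, HISAT2 2.2.0, featureCounts 2.0.0 and DESeq2 1.34.0, with the build GRCh38.p13. Their settings, the strand setting and the annotation release are not given in the sources used here. Reads of a gene and of an overlapping antisense gene therefore cannot be told apart, and genes with near-identical copies are named as uncertain. The file pairs counts with gene symbols alone, so genes are named by symbol, and coordinates come from GENCODE 29 on GRCh38, matched by symbol.

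Groups came from the labels, with 3 replicates in each of 6 groups. Library totals ran from 36.5 to 39.8 M counts, and genes kept by the filter held 99.92% to 99.95% of them. Replicates of a group differed by more than counting error (chi-square per degree of freedom from 3.93 to 42.6 over genes with at least 20 counts summed over a pair of replicates), so that each was counted as a separate library. Intervals and standard errors cover counting error and the spread between these libraries only.

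The main test was edgeR 4.0.16 (R 4.3.3): TMM scaling, the filterByExpr filter with a minimum count of 10, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment over all genes tested, with a gene called at an adjusted p below 0.05. The 12 HT-29 iZEB1 libraries were fitted together by group (16978 genes), the 6 SW620 libraries alone (17147 genes), and the comparison of the lines in all 18 libraries (19107 genes). The typical spread between replicates was 7.82%, 5.1% and 7.04% of a gene's level in these fits (biological coefficient of variation). Adjusted p-values of genes are from these fits. Standard errors were taken as the size of the unshrunken log2 fold change divided by the square root of its F statistic. The printed fold changes include the small prior count that edgeR adds, so at low counts they do not match these standard errors exactly. CPM are counts scaled to the TMM effective library size, given as mean ± SD of 3 libraries. In counts simulated from these libraries with 50 genes changed at each fold, the test recovered 66% of 1.5-fold and 74% of 2-fold changes for DOX in DMSO over 16978 genes, 64% and 76% for DOX in RepSox over 16978 genes, and 52% and 80% for RepSox in SW620 over 17147 genes. For the difference between the lines, over 19107 genes, it recovered 38% and 58%. False calls made up 3.49% of the simulated calls for that difference, 5.76% for DOX in DMSO and 7.95% for RepSox in SW620. The highest share was 8.59%, for RepSox without DOX, so it could exceed the threshold of 0.05. Except for DOX in RepSox, far fewer genes changed in the simulations than were called in the data. The adjusted threshold is stricter with fewer changed genes, so the recovered shares do not measure recovery in those comparisons.

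The comparisons, the tests, the alternatives, the rule for named genes and 24 gene lists were fixed before the data were examined. ZEB1, CDH1, VIM, SMAD7, ID1 and CYP1A1 are given in every comparison, and 1 more gene of this part of the rule and some list members are not reported here. Further, the 8 called genes with the largest rise and the 8 with the largest fall are named, provided that the higher group had at least 5 CPM and, except for the interaction and the difference between lines, that the libraries of the 2 groups did not overlap, which chance gives for 10% of genes with 3 against 3. Up to 4 called members of each list could be named as well. The lists cover epithelial, mesenchymal and EMT transcription factor genes. They also cover targets of TGF-β, BMP, the aryl hydrocarbon receptor, NRF2, ATF4, p53, YAP/TAZ, NF-κB, interferon, WNT and ERK signalling. The rest are unfolded protein response, cell cycle, intestinal differentiation, sterol synthesis, hypoxia and glycolysis, mitochondrially encoded and replication-dependent histone genes, and markers of fibroblasts, leukocytes and endothelial cells. Some genes are in more than 1 list: TAGLN is in the mesenchymal and TGF-β lists, and AXL in the mesenchymal and YAP/TAZ lists. The list tests are therefore not independent of each other. Lists with at least 5 tested genes were tested against the other genes with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, then again with the correlation estimated from the data. The second form is stricter for lists whose genes vary together. A list call that holds with it is given as such, and 12 of 78 list calls did. Counts adjusted over the list alone are printed beside counts over all genes, in the order in which the directions are named.

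Opposite and same-direction moves of genes in 2 comparisons were counted beside the number that independent lists would share. Within HT-29 iZEB1 they were also set beside 20 simulations of unchanged groups with the same sharing of libraries. Alternatives were DESeq2 1.42.0, RLE scaling, library totals alone, no low-count filter, a minimum count of 50, the replicate number as a block, each library left out in turn, the 2 compared groups alone, 1 fit of all libraries, fry in place of camera, an adjusted p below 0.01 and a fold threshold. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.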

Results

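Gene counts from RNA sequencing were analysed for 18 libraries of 2 human colorectal cancer cell lines, in 6 groups of 3. HT-29 iZEB1 is a form of the HT-29 line in which doxycycline (DOX) switches on ZEB1, a zinc-finger transcription factor that represses epithelial genes during the epithelial-mesenchymal transition (EMT). RepSox is a small-molecule inhibitor of ALK5, the type I receptor for TGF-β. HT-29 iZEB1 cells had either the vehicle DMSO or RepSox, each without and with DOX, and SW620 cells had DMSO or RepSox with no inducer. RepSox was given at 10 µM for 24 h and DOX at 1 µg per ml. The labels' treatment protocol gives 24 h of DOX and the series' design text gives 48 h. The HT-29 iZEB1 libraries held 36.5 to 39.8 M counts each and the SW620 libraries 37.2 to 37.5 M. On the first principal component of the 12 HT-29 iZEB1 libraries, which carried 49.7% of the variance, the 3 libraries with DOX and DMSO lay between -63.8 and -61.6. Those with DMSO alone lay between 2.9 and 6.03, those with RepSox alone between 32.8 and 34.1, and those with DOX and RepSox between 24 and 26.8. The labels do not say whether replicates are separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

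The induced gene was examined first. ZEB1 (chromosome 10, 31318495 to 31529814, plus strand, protein-coding, GRCh38) stood at 8.38 ± 1.6 CPM (normalised counts, SD, n = 3) in HT-29 iZEB1 with DMSO alone and at 372 ± 7.2 CPM (SD, n = 3) with DOX and DMSO. With DOX and RepSox it stood at 15.6 ± 1.4 CPM (SD, n = 3), and with RepSox alone at 5.25 ± 0.32 CPM (SD, n = 3). SW620 had 22.4 ± 2.7 CPM (SD, n = 3) in DMSO and 24.7 ± 0.85 CPM (SD, n = 3) in RepSox. CDH1 (chromosome 16, 68737225 to 68835548, plus strand, protein-coding, GRCh38), which encodes the adhesion molecule E-cadherin, stood at 461 ± 16 CPM with DMSO alone, 228 ± 5.5 with DOX and DMSO, 342 ± 9.4 with DOX and RepSox and 376 ± 9.1 with RepSox alone (SD, n = 3 each). In SW620 it was at 10.4 ± 1.9 CPM in DMSO and 19 ± 0.34 CPM in RepSox (SD, n = 3 each). The gene counts do not separate transcripts of the inducible ZEB1 from those of the cells' own gene.

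**Figure D1:**
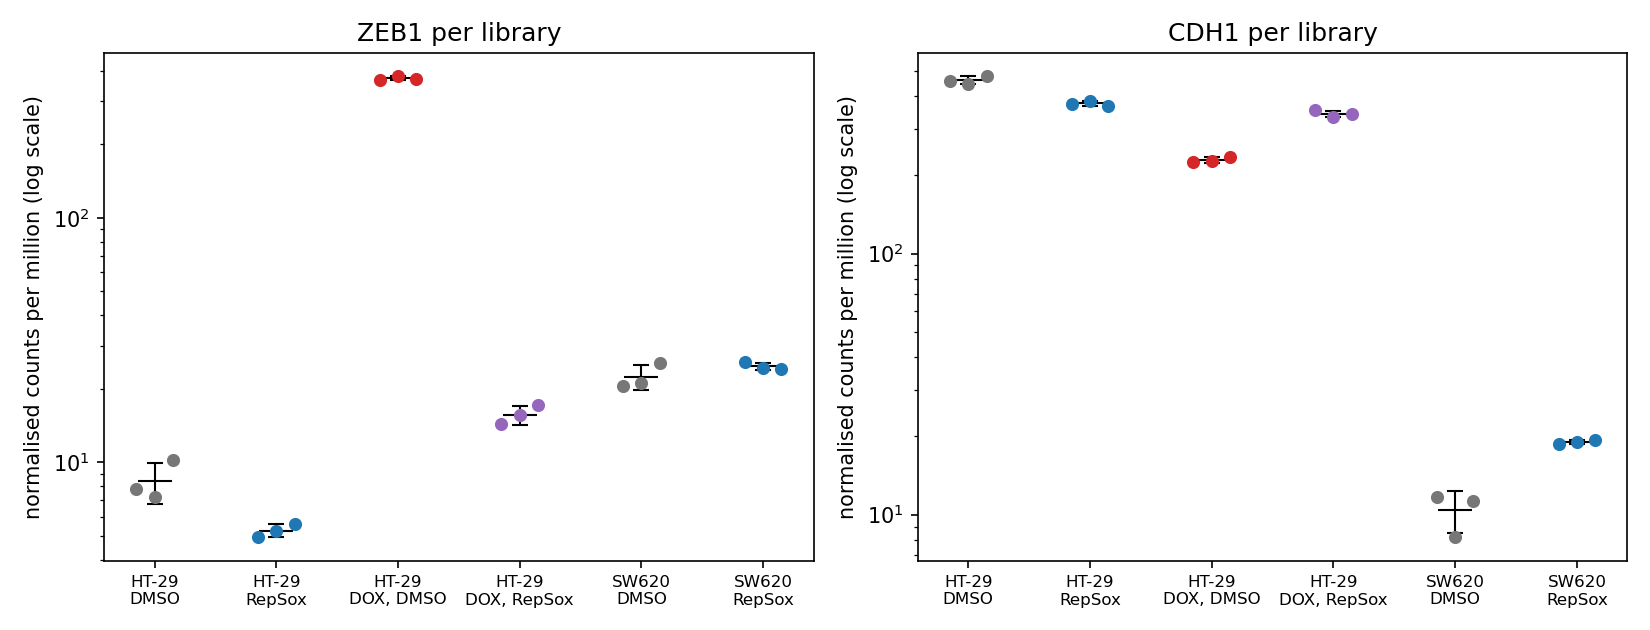
CPM of ZEB1 and CDH1 on log axes, 1 point per library, in the 6 groups, with horizontal marks at the group mean and bars of 1 SD (n = 3). ZEB1 averages 372 CPM with DOX and DMSO against 15.6 CPM with DOX and RepSox, and CDH1 averages 228 against 342 CPM.

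The first comparison asked what DOX changed in HT-29 iZEB1 cells kept in DMSO. ZEB1 was 44.3-fold higher with DOX (log2 fold change 5.47, SE 0.1, adjusted p = 2.4e-17, n = 3 in each group) and CDH1 was 2.02-fold lower (log2 -1.01, SE 0.054, adjusted p = 3.61e-11). Among called genes with at least 5 CPM in the higher group and no overlap between the libraries of the groups, the largest rise was that of ATOH8 (chromosome 2, 85751344 to 85788066, plus strand, protein-coding, GRCh38), a basic helix-loop-helix transcription factor, which went from 22 counts summed over 3 libraries to 1216 counts, 48.7-fold higher (log2 5.61, SE 0.26, adjusted p = 3.97e-12). Others of these that rose were ANGPTL2, a secreted angiopoietin-like protein (24.3-fold), the actin-associated SYNPO (15.5-fold), the CDC42 exchange factor DOCK11 (14.3-fold), HEG1 (10.9-fold), EMP3 (10.1-fold) and NAV3 (8.47-fold). The largest falls within the same limits were those of MAB21L4 (38.9-fold lower), the phospholipase A2 gene PLA2G4F (32-fold lower), S100A14 (22.4-fold lower), the dynein adaptor BICDL2 (20.9-fold lower), the membrane serine protease TMPRSS4 (19.3-fold lower), the flippase subunit TMEM30B (17.8-fold lower), the enteric hormone FGF19 (15.9-fold lower) and C1orf210 (15.3-fold lower). S100A14 (chromosome 1, 153614255 to 153616986, minus strand, protein-coding, GRCh38) went from 43.1 ± 1 to 1.92 ± 0.22 CPM (SD, n = 3). VIM, the mesenchymal filament gene vimentin, stayed below 1 CPM with and without DOX (0.849 ± 0.37 against 0.314 ± 0.14, SD, n = 3; adjusted p = 0.00838, and 0.0537 without minusDOX_DMSO replicate 2).

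Genes of the epithelial list fell nearly as a block. Of 48 tested members of the epithelial list, 46 fell with DOX and 2 did not pass the test (46 fell when adjusted over the list alone), with a median log2 change of -1.47 (camera adjusted p = 1.83e-106, and adjusted p = 5.39e-05 with an estimated correlation). Examples beside S100A14 and TMEM30B are AP1M2, an epithelial clathrin adaptor subunit (7.1-fold lower), and the tight-junction gene MARVELD3 (7.42-fold lower). Of 25 tested mesenchymal genes 14 rose and 2 fell (15 and 3 adjusted over the list alone, camera adjusted p = 0.000379, and adjusted p = 0.0663 with an estimated correlation). LGALS1, which encodes galectin-1, rose 3.6-fold, the receptor tyrosine kinase gene AXL 2.88-fold and the 5'-nucleotidase gene NT5E 1.72-fold. Among 6 tested EMT transcription factors other than ZEB1, ETS1 rose 2.57-fold and SNAI1 was 1.89-fold lower. The list did not pass (1 and 2 adjusted over the list alone, camera adjusted p = 0.54).

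The WNT target and stem cell list rose with DOX, 9 of 17 tested genes higher and 2 lower (9 and 2 adjusted over the list alone, camera adjusted p = 6.14e-05, and adjusted p = 0.0663 with an estimated correlation). SOX4 went from 81.8 ± 1.9 to 216 ± 7 CPM (SD, n = 3), AXIN2, a feedback inhibitor of WNT signalling, rose 2.1-fold and the stem cell receptor LGR5 1.96-fold, while MYC was 1.69-fold lower. YAP/TAZ targets rose in 12 of 17 and fell in 2 (12 and 2 adjusted over the list alone, camera adjusted p = 0.00143, and adjusted p = 0.058 with an estimated correlation), with MYOF 1.59-fold higher. The p53 targets rose in 11 of 23 and fell in 3 (11 and 3 adjusted over the list alone, camera adjusted p = 0.00617, and adjusted p = 0.0663 with an estimated correlation), led by BTG2 (2.97-fold higher) and TP53INP1 (7.1-fold higher). Replication-dependent histone genes, whose mRNAs for the most part lack poly(A) tails, rose in 6 of 11 (8 adjusted over the list alone, camera adjusted p = 0.00876, and adjusted p = 0.082 with an estimated correlation), among them H2AC6 (2.46-fold) and H2BC5 (2.74-fold).

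The 5 lists that follow had a lower direction with DOX and passed camera with the preset correlation, and none of them passed with an estimated one. The cell cycle list fell in 26 of 36 (26 adjusted over the list alone, camera adjusted p = 7.81e-11, and adjusted p = 0.0663 with an estimated correlation). Among them were the replication licensing gene CDC6 (2.22-fold lower), the clamp PCNA (1.91-fold lower), the helicase subunit MCM4 (1.97-fold lower) and GINS2 (2.23-fold lower). Sterol synthesis genes fell in 21 of 25 (21 adjusted over the list alone, camera adjusted p = 1.26e-07, and adjusted p = 0.0663 with an estimated correlation), with MVK 2.19-fold lower. The hypoxia and glycolysis list fell in 15 of 24 and rose in 2 (17 and 2 adjusted over the list alone, camera adjusted p = 0.000434, and adjusted p = 0.269 with an estimated correlation), with hexokinase gene HK2 2.17-fold lower. The ATF4 stress response list fell in 15 of 28 and rose in 4 (17 and 4 adjusted over the list alone, camera adjusted p = 0.00413, and adjusted p = 0.269 with an estimated correlation), with TRIB3 2.12-fold lower. The unfolded protein response list fell in 11 of 19 and rose in 1 (11 and 1 adjusted over the list alone, camera adjusted p = 0.048, and adjusted p = 0.268 with an estimated correlation), with the chaperone HSPA5 1.39-fold lower.

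Several lists did not move 1 way with DOX. The TGF-β list had 16 higher and 9 lower of 31 (16 and 9 adjusted over the list alone, camera adjusted p = 0.555): SKIL, which encodes a SMAD co-repressor, rose 1.8-fold and the integrin subunit ITGB6 was 9.82-fold lower. SMAD7 rose (log2 0.32, SE 0.091, adjusted p = 0.00835), ID1 had a log2 change of 0.07 (SE 0.09, adjusted p = 0.6), and CYP1A1 stayed below 1 CPM (log2 -0.30, SE 0.53, adjusted p = 0.691). The BMP list had 5 higher and 1 lower of 11 (camera adjusted p = 0.0981; 5 and 1 adjusted over the list alone), the lower gene being ID2 (2.83-fold). Intestinal differentiation genes had 10 higher and 12 lower of 28 (11 and 13 adjusted over the list alone, camera adjusted p = 0.891), with CDH17 6.4-fold higher and villin gene VIL1 4.19-fold lower. The ERK output list had 9 higher and 9 lower of 21 (9 and 9 adjusted over the list alone, camera adjusted p = 0.54). The aryl hydrocarbon receptor list had 3 and 4 of 11 (4 and 4 adjusted over the list alone, camera adjusted p = 0.555), with a median of 0.13 and a mean of -0.08. The NRF2 list had 5 and 5 of 21 (6 and 5 adjusted over the list alone, camera adjusted p = 0.922), with a median of -0.06 and a mean of 0.03. Of 17 NF-κB and cytokine genes 2 were higher and 1 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.555).

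Interferon genes were higher in 9 of 29 (7 adjusted over the list alone, camera adjusted p = 0.109), and this list differed between replicates: its mean log2 deviation from the group was 0.61 in plusDOX_DMSO replicate 2, -0.36 in replicate 3 and -0.25 in replicate 1. Mitochondrially encoded mRNAs had a median log2 change of -0.19 over 13 genes (camera adjusted p = 0.555), with deviations of -0.53 in plusDOX_DMSO replicate 2 and 0.41 in replicate 3. Markers of other cell types were low: the medians of the fibroblast, leukocyte and endothelial lists were at most 0.131 CPM in each of the 6 groups. In HT-29 iZEB1 each of these lists had fewer than 5 tested members and no list test. The exceptions included LYZ, which encodes lysozyme, at 1310 ± 37 CPM without and 1730 ± 14 CPM with DOX in HT-29 iZEB1 (SD, n = 3). ESAM stood at 34.7 to 58 CPM in the HT-29 iZEB1 groups and FBLN1 at 55.2 and 57.8 CPM in the SW620 groups.

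In all, edgeR's quasi-likelihood test called 6853 of 16978 genes for DOX in DMSO (40.4%), 3265 higher and 3588 lower, and 1350 of them changed at least 2-fold. The share of higher calls was 47.6% and became 59.5% when libraries were scaled by their totals alone. DOX and ZEB1 cannot be separated here, since HT-29 cells without the inducible gene were not analysed.

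**Figure D2:**
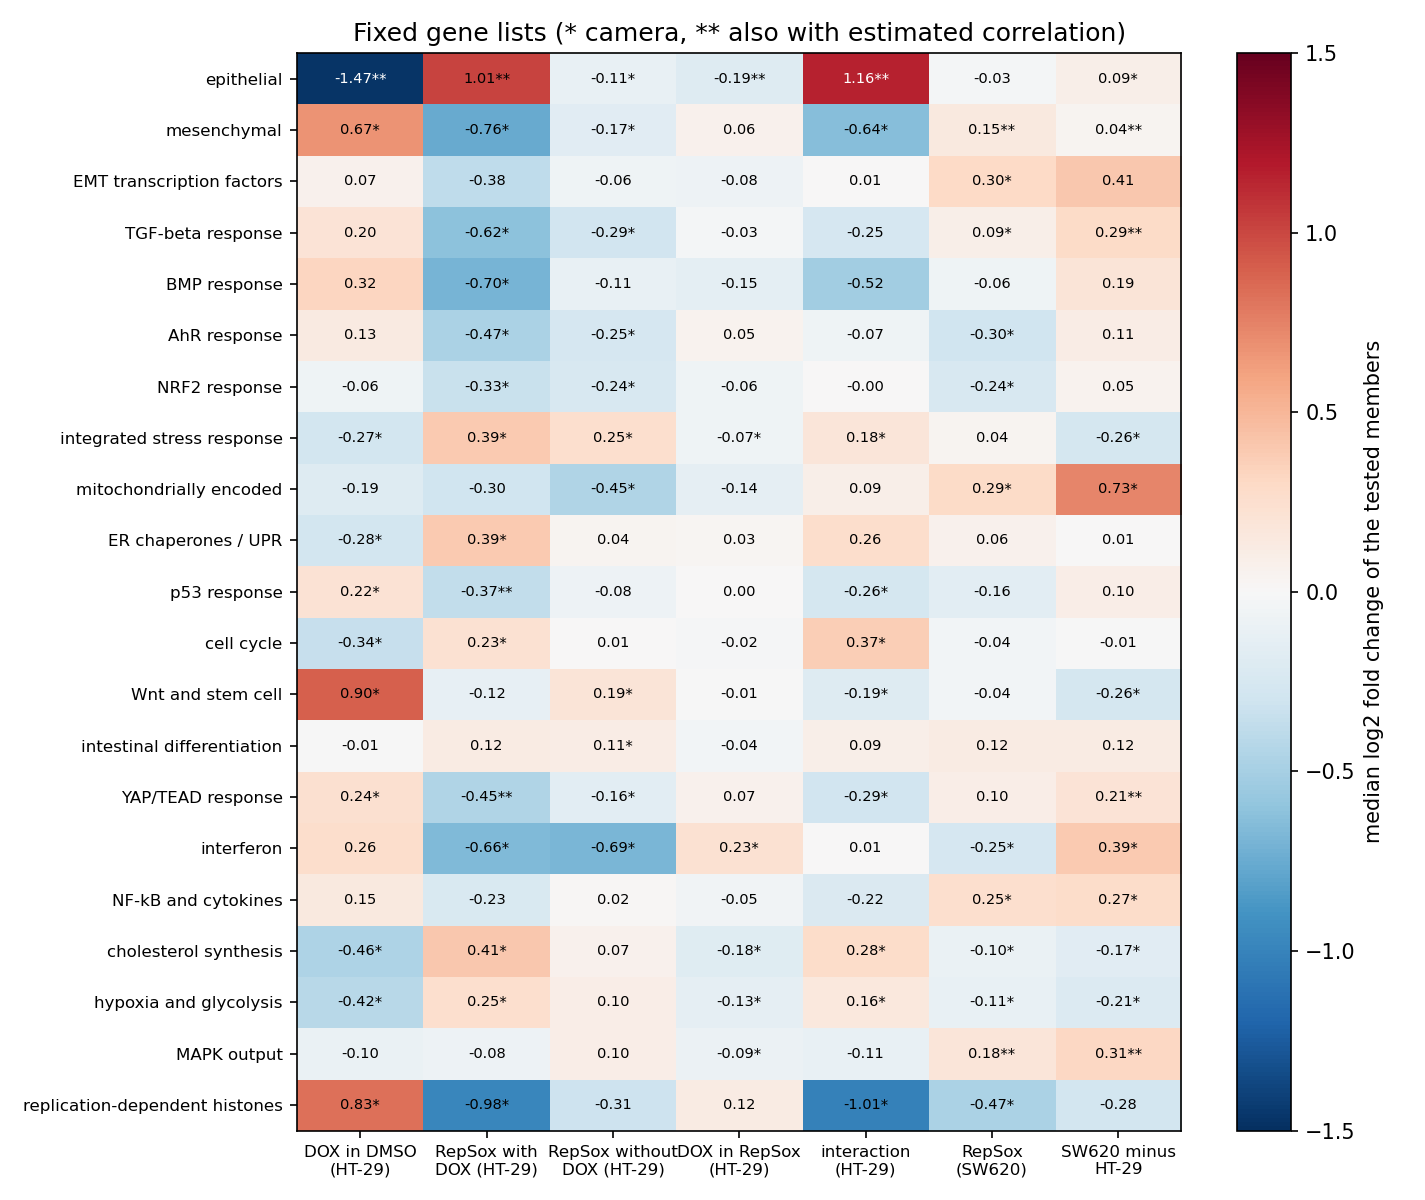
Median log2 fold change of the tested members of 21 gene lists (lines) in the 7 comparisons (columns), with 1 star where camera passed and 2 stars where it also passed with an estimated correlation. The epithelial list has medians of -1.47 with DOX in DMSO, 1.01 with RepSox beside DOX and -0.19 with DOX in RepSox.

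The next comparison asked what RepSox changed in HT-29 iZEB1 cells that also had DOX. ZEB1 was 23.8-fold lower with RepSox (log2 -4.57, SE 0.098, adjusted p = 4.02e-16, n = 3 in each group) and CDH1 was 1.5-fold higher (log2 0.58, SE 0.054, adjusted p = 4.45e-08). ATOH8 dropped from 1216 counts over 3 libraries to 9, BMF, a pro-apoptotic BH3-only gene, was 26.2-fold lower, ANGPTL2 19.7-fold lower, the acid sphingomyelinase gene SMPD1 16.4-fold lower, EMP3 14.1-fold lower, TP53INP1 13.9-fold lower and SYNPO 12.6-fold lower. FGF19 rose 17-fold, from 7.19 ± 1 to 122 ± 11 CPM (SD, n = 3). Other rises were those of the adhesion genes CEACAM6 (14.3-fold) and CEACAM5 (10.8-fold), which are close paralogs whose counts are uncertain to that extent, the sulfotransferase CHST4 (12.1-fold), the nucleoside transporter SLC28A3 (10.6-fold), BICDL2 (9.73-fold), TMEM30B (8.63-fold) and MIR205HG, the host gene of a microRNA (8.56-fold). SMAD7 was 2.28-fold lower (adjusted p = 5.74e-09) and ID1 2.51-fold lower (adjusted p = 1.33e-09). VIM had a log2 change of -0.76 (SE 0.38, adjusted p = 0.102, and 0.0208 without plusDOX_DMSO replicate 1). CYP1A1 had a log2 change of -1.57 below 1 CPM (SE 0.65, adjusted p = 0.0464). Its call was lost with DESeq2 (0.0631) and without plusDOX_DMSO replicate 1 (0.197) or replicate 3 (0.0543), or plusDOX_RepSox replicate 2 (0.0838) or replicate 3 (0.164).

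Epithelial genes rose with RepSox in 43 of 48 and fell in 1 (43 and 1 adjusted over the list alone), with a median log2 change of 1.01 (camera adjusted p = 2.67e-44, and adjusted p = 0.00155 with an estimated correlation). MARVELD3 rose 6.75-fold, BSPRY 7.39-fold and AP1M2 4.72-fold. The p53 targets fell in 14 of 23 and rose in 2 (14 and 2 adjusted over the list alone, camera adjusted p = 0.000647, and adjusted p = 0.0454 with an estimated correlation), with the pro-apoptotic gene BBC3 2.07-fold and BTG2 1.6-fold lower, and AEN 2.29-fold higher. YAP/TAZ targets fell in 11 of 17 and rose in 5 (11 and 5 adjusted over the list alone, camera adjusted p = 0.00092, and adjusted p = 0.0454 with an estimated correlation). MYOF was 2.79-fold, AXL 3.51-fold and NT5E 1.8-fold lower, and FJX1 was 3.52-fold higher.

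Other lists passed only with the preset correlation. The TGF-β list fell in 20 of 31 and rose in 7 (21 and 7 adjusted over the list alone, camera adjusted p = 0.00742, and adjusted p = 0.214 with an estimated correlation). PPP1R15A was 2.13-fold lower, while ITGB6 (7.83-fold) and VEGFA (2.25-fold) rose. The BMP list fell in 7 of 11 and rose in 1, ID2 at 3.94-fold higher (7 and 1 adjusted over the list alone, camera adjusted p = 0.00422, and adjusted p = 0.214 with an estimated correlation). Mesenchymal genes fell in 12 of 25 and rose in 2 (12 and 2 adjusted over the list alone, camera adjusted p = 0.000365, and adjusted p = 0.0895 with an estimated correlation), with LGALS1 5.84-fold lower. Cell cycle genes rose in 20 of 36 and fell in 1 (20 and 1 adjusted over the list alone, camera adjusted p = 4.1e-07, and adjusted p = 0.123 with an estimated correlation), with CDC6 2.43-fold and MCM3 2.31-fold higher. Histone genes fell in 9 of 11 (9 adjusted over the list alone, camera adjusted p = 0.00422, and adjusted p = 0.0903 with an estimated correlation), with H2AC6 3.4-fold lower. Interferon genes fell in 18 of 29 (19 adjusted over the list alone, camera adjusted p = 0.00128, and adjusted p = 0.514 with an estimated correlation), with STAT2 2.38-fold lower, in a list that differed between replicates as given above. The ATF4 list rose in 15 of 28 and fell in 3 (16 and 3 adjusted over the list alone, camera adjusted p = 0.000251, and adjusted p = 0.168 with an estimated correlation), with the serine synthesis gene PSAT1 2.33-fold higher.

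For RepSox with DOX, edgeR's quasi-likelihood test called 8864 of 16978 genes (52.2%), 4543 higher and 4321 lower, and 1967 changed at least 2-fold. The share of higher calls was 51.3%, and 43.7% when libraries were scaled by their totals alone. The study's design sets this treatment against the induction, so the directions were compared gene by gene. Of the 6853 genes called with DOX in DMSO, 5479 (80%) moved the opposite way with RepSox and 112 (1.63%) the same way: 2577 of the 3265 risers fell and 2902 of the 3588 fallers rose. Independent lists of these sizes would give 831 and 960 opposite moves. Across 16978 genes, which are not independent replicates, the fold changes had a Pearson r of -0.79 and a Spearman rho of -0.77. The plusDOX_DMSO libraries enter both comparisons with opposite sign, and unchanged groups simulated 20 times gave a mean r of -0.49, a covariance of -0.0241 and a mean of 0.05 opposite calls. The simulated groups held no effects, so few genes could be called there. The simulated count is therefore not a chance level for opposite calls where effects are real. The observed covariance was -0.397, and -0.373 after the simulated one was taken off. The 3 shared libraries do not give 2 sets of at least 2 libraries and were not split, so part of the excess of opposite calls over independent lists may come from them. RepSox without DOX, where minusDOX_DMSO libraries are shared with the same sign, moved 1845 of the 6853 genes the opposite way and 723 the same way. Of the risers 820 fell and of the fallers 1025 rose, against 418 and 447 for independent lists. The simulated mean r was 0.51 here and the observed r was -0.00. RepSox in SW620 shares no library with the DOX comparison. Of 6255 DOX-called genes tested in both lines, 1075 moved the opposite way there and 574 the same way (r = -0.12). Of the risers 498 fell and of the fallers 577 rose, against 282 and 341 for independent lists. Same-way moves numbered 325 risers and 249 fallers, against 301 and 319.

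**Figure D3:**
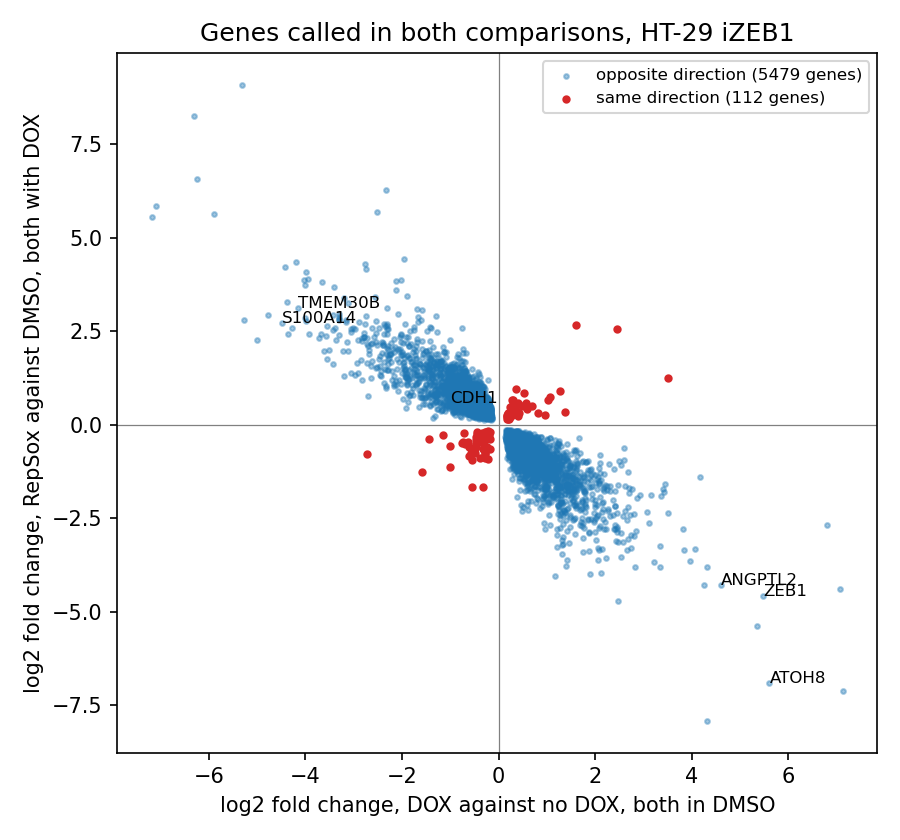
Log2 fold change with DOX in DMSO (horizontal axis) against that with RepSox beside DOX (vertical axis), 1 point for each of the 5591 genes called in both. Blue points are the 5479 genes with opposite directions and red points the 112 genes with the same direction.

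RepSox was next compared with DMSO in HT-29 iZEB1 without DOX. MRAS (chromosome 3, 138347648 to 138405534, plus strand, protein-coding, GRCh38), which encodes a Ras-related GTPase, rose from 0.887 ± 0.1 to 16.2 ± 0.87 CPM (SD, n = 3), 18.2-fold (log2 4.18, SE 0.14, adjusted p = 1.32e-12). Among called genes with at least 5 CPM in the higher group and no overlap between libraries, next came CEACAM6 (4.13-fold), FCGBP, a mucus protein gene (3.64-fold), CHST4 (3.6-fold), CEACAM5 (3.55-fold), the receptor tyrosine kinase gene TEK (3.53-fold), the alcohol dehydrogenase ADH1C, which has close paralogs and is uncertain (3.4-fold), and the GABA receptor subunit GABRP (3.19-fold). The falls within these limits were led by the sterol sulfotransferase SULT2B1 (6.89-fold lower), BMF (6.28-fold lower), PLA2G4F (4.64-fold lower), SCEL (4.62-fold lower), CYP4F12, a cytochrome P450 with close paralogs (4.28-fold lower), the immediate-early gene EGR1 (3.7-fold lower), ANTXR2 (3.56-fold lower) and the lysyl oxidase-like gene LOXL4 (3.44-fold lower). ZEB1 was 1.6-fold lower (log2 -0.67, SE 0.11, adjusted p = 0.000246) and CDH1 1.23-fold lower (log2 -0.29, SE 0.054, adjusted p = 0.000529). ID1, a BMP and SMAD target, went from 45.5 ± 3.8 to 17.9 ± 0.62 CPM (SD, n = 3; adjusted p = 1.67e-08), and SMAD7 was 1.41-fold lower (adjusted p = 0.000727). CYP1A1 fell from 0.499 ± 0.056 to 0.0555 ± 0.055 CPM (SD, n = 3; adjusted p = 0.00447), and VIM had a log2 change of -0.29 (SE 0.48, adjusted p = 0.709).

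Interferon-stimulated genes fell in 18 of 29 (22 adjusted over the list alone, camera adjusted p = 1.75e-08, and adjusted p = 0.336 with an estimated correlation), among them OAS1 (1.8-fold lower), IFIT1 (2.03-fold lower) and IRF9 (1.98-fold lower). Their mean log2 deviation lay between -0.23 and 0.24 within the DMSO libraries. NRF2 targets fell in 10 of 21 (14 lower and 2 higher adjusted over the list alone, camera adjusted p = 4.57e-05, and adjusted p = 0.214 with an estimated correlation), with the quinone reductase NQO1 1.42-fold lower. Aryl hydrocarbon receptor targets fell in 6 of 11 and rose in 2 (6 and 2 adjusted over the list alone, camera adjusted p = 0.000989, and adjusted p = 0.109 with an estimated correlation), with CYP1B1 2.54-fold lower. The TGF-β list fell in 14 of 31 and rose in 4 (15 and 6 adjusted over the list alone, camera adjusted p = 0.00508, and adjusted p = 0.214 with an estimated correlation), JUNB being 2.18-fold lower and WNT11 2.42-fold higher. The ATF4 list rose in 11 of 28 (14 adjusted over the list alone, camera adjusted p = 0.000146, and adjusted p = 0.214 with an estimated correlation), with PSAT1 1.51-fold higher. WNT and stem cell genes rose in 5 of 17 and fell in 2 (9 and 2 adjusted over the list alone, camera adjusted p = 0.00508, and adjusted p = 0.214 with an estimated correlation), with PROM1 2.09-fold higher. Mitochondrially encoded mRNAs fell in 2 of 13 (7 adjusted over the list alone, camera adjusted p = 0.0124, and adjusted p = 0.601 with an estimated correlation), with a mean deviation of -0.48 in minusDOX_RepSox replicate 1. Epithelial genes fell in 20 of 48 and rose in 3 (21 and 3 adjusted over the list alone, camera adjusted p = 0.000795, and adjusted p = 0.241 with an estimated correlation), with KRT19 1.69-fold lower. No list test for this comparison passed with an estimated correlation (limma's camera), against 11 of the 21 lists with the preset one.

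For RepSox without DOX, edgeR's quasi-likelihood test called 4290 of 16978 genes (25.3%), 2114 higher and 2176 lower, and 444 changed at least 2-fold. Of the calls of the 2 RepSox comparisons in HT-29 iZEB1, which share no library, 3269 genes moved the same way and 254 opposite ways (r = 0.49 across genes, which are not independent replicates). Higher in both were 1676 and lower in both 1593, against 566 and 554 for independent lists.

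DOX was then compared with no DOX under RepSox. ZEB1 was 2.98-fold higher with DOX (log2 1.57, SE 0.11, adjusted p = 1.37e-07, n = 3 in each group). S100A14 fell from 31.4 ± 1.4 to 12.6 ± 1.4 CPM (SD, n = 3), 2.49-fold (log2 -1.31, SE 0.087, adjusted p = 1.37e-07), TMEM125 was 2.3-fold lower, PHGR1 2.15-fold lower, SYT8 1.84-fold lower, FUT1, a fucosyltransferase gene, 1.79-fold lower, and BICDL2 and TMEM30B 1.72-fold lower. LGR5 rose 1.72-fold, from 53.9 ± 2.7 to 92.7 ± 4.1 CPM (SD, n = 3; adjusted p = 4.94e-06), and the efflux pump gene ABCC4 rose 1.42-fold. The rises of RPL9P7 and EEF1A1P6, pseudogenes whose reads can belong to their parent genes, of FYN, BBS4 and GNE, and the fall of MUC1, were each lost when some of the libraries were left out (adjusted p from 0.00587 for GNE to 0.0373 for FYN with all libraries). CDH1 had a log2 change of -0.13 (SE 0.054, adjusted p = 0.286), ID1 0.08 (SE 0.097, adjusted p = 0.726), and VIM 0.96 (SE 0.45, adjusted p = 0.343). CYP1A1 stood at 0.135 against 0.0555 CPM (adjusted p = 0.541). SMAD7 had a log2 change of -0.37 (SE 0.097, adjusted p = 0.109), which passed without plusDOX_RepSox replicate 1 (adjusted p = 0.0152) and with DESeq2 (adjusted p = 0.0298).

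Epithelial genes fell in 10 of 48 (23 lower and 3 higher adjusted over the list alone), with a median log2 change of -0.19 (camera adjusted p = 1.28e-24, and adjusted p = 0.0141 with an estimated correlation). AP1M2 and the claudin gene CLDN7 were each 1.47-fold lower. Sterol synthesis genes had a median of -0.18, with 14 of 25 lower adjusted over the list alone and no call over all genes (camera adjusted p = 5.74e-12, and adjusted p = 0.0727 with an estimated correlation). Interferon genes had a median of 0.23 (1 higher adjusted over the list alone, camera adjusted p = 4.51e-06, and adjusted p = 0.462 with an estimated correlation).

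With edgeR's quasi-likelihood test, 81 of 16978 genes (0.477%) were called for DOX under RepSox, 16 higher and 65 lower, 8 of them by at least 2-fold. Of the 81, 71 moved the same way as with DOX in DMSO, 2 the opposite way, and 8 were called only under RepSox. Among the genes that rose with DOX in DMSO, ZEB1 left out, the median log2 change with DOX went from 0.52 in DMSO to 0.07 in RepSox, and among those that fell from -0.48 to -0.07. The count rests on single libraries: it was 1670 without plusDOX_RepSox replicate 1, 27 without its replicate 2 and 41 without its replicate 3, and 36, 41 and 43 without minusDOX_RepSox replicates 1, 2 and 3. Of the 1670, 1664 were also tested with all libraries, 658 of them higher and 1006 lower, and 746 moved the same way as with DOX in DMSO, 133 the opposite way, and 785 were not called in DMSO. DESeq2 called 264, and 2388 genes had an unadjusted p under 0.05. The epithelial list fell in 6 to 20 of its 48 genes over the same omissions, with medians of -0.20 to -0.15.

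**Figure D4:**
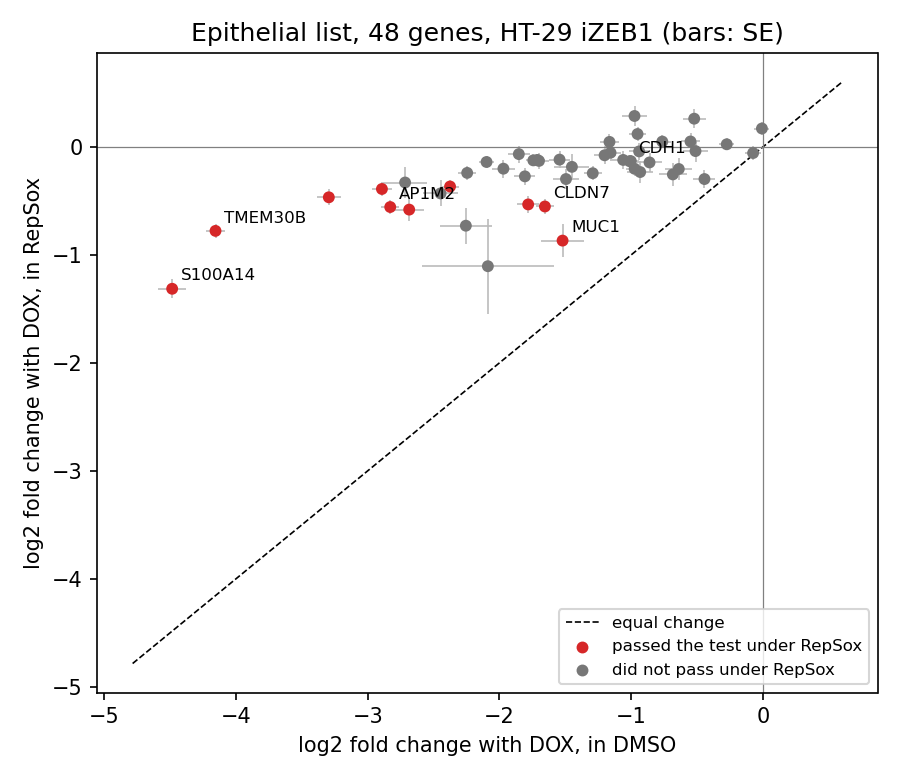
Log2 fold change with DOX in DMSO (horizontal axis) against that with DOX in RepSox (vertical axis) for the 48 epithelial list genes, with bars of 1 SE and a dashed line of equal change. Red points are the 10 genes that passed the test under RepSox, S100A14 lowest at -1.31.

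The interaction tested whether the effect of RepSox differed with and without DOX. It was negative for ZEB1 (log2 -3.90, SE 0.15, adjusted p = 2.85e-12) and positive for CDH1 (log2 0.88, SE 0.076, adjusted p = 1.14e-07), so RepSox lowered ZEB1 more with DOX than without it, and CDH1 rose with RepSox where DOX was present and fell where it was not. Among called genes with at least 5 CPM in the highest group, the largest positive interactions were those of MAB21L4 (4.52), PLA2G4F (4.49), BICDL2 (3.60), TMPRSS4 (3.56), FGF19 (3.53), TMEM30B (3.38), the pseudogene MUC20P1, whose reads may be shared with MUC20 (3.32), and C1orf210 (3.19), all on the log2 scale. The largest negative ones beside ZEB1 were those of ANGPTL2 (-4.44), SYNPO (-3.22), DOCK11 (-3.15), EMP3 (-3.03), HEG1 (-3.00), NAV3 (-2.71) and MAP1A, a microtubule-binding protein gene (-2.70). ATOH8, at -3.65, was not called (SE 1.4, adjusted p = 0.0937). SMAD7 also differed (log2 -0.69, SE 0.13). ID1 (0.02, SE 0.13, adjusted p = 0.95), VIM (-0.46, SE 0.62, adjusted p = 0.651) and CYP1A1 (1.54, SE 1.1, adjusted p = 0.326) did not pass.

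Epithelial genes had a positive interaction in 44 of 48 (45 adjusted over the list alone), with a median of 1.16 (camera adjusted p = 6.26e-100, and adjusted p = 8.22e-05 with an estimated correlation). ESRP1, an epithelial splicing regulator, had 1.96, MARVELD3 2.50 and BSPRY 2.83. Cell cycle genes were positive in 23 of 36 (23 adjusted over the list alone, camera adjusted p = 2.94e-12, and adjusted p = 0.0766 with an estimated correlation), with CDC6 at 1.13. WNT and stem cell genes were negative in 7 of 17 and positive in 1 (7 and 2 adjusted over the list alone, camera adjusted p = 0.000644, and adjusted p = 0.106 with an estimated correlation), with SOX4 at -1.43 and AXIN2 at -1.19. The TGF-β list was negative in 10 of 31 and positive in 2 (13 and 3 adjusted over the list alone, camera adjusted p = 0.273). By edgeR's quasi-likelihood test 3834 of 16978 genes had an interaction, 2202 positive and 1632 negative, 894 of at least 2-fold. The positive share was 57.4%, and 47% when libraries were scaled by their totals alone.

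In SW620 the effect of RepSox was asked in cells with no inducible gene. TAGLN (chromosome 11, 117199321 to 117204782, plus strand, protein-coding, GRCh38), which encodes the actin-binding protein transgelin, rose from 14 ± 2 to 58.6 ± 1.5 CPM (SD, n = 3), 4.2-fold (log2 2.07, SE 0.076, adjusted p = 3.18e-15). MDGA1 rose 4.96-fold, the endothelin gene EDN2 4.88-fold, ANKRD22 3.85-fold, SPOCD1 3.51-fold and the arginine deiminase gene PADI1 3.21-fold. KRT87P, a keratin pseudogene (3.05-fold; adjusted p = 0.000108, and 0.0509 with DESeq2), and the antisense gene MIR1-1HG-AS1 (3.02-fold) also rose, both uncertain as to which gene their reads belong to. EGR1 was 3.12-fold lower, ANK3, which encodes ankyrin-G, 2.53-fold lower, CRB2 2.42-fold lower, PKD1L2 2.28-fold lower and the folate receptor gene FOLR1 2.18-fold lower. The lower counts of CCT7P2 (2.41-fold), BCAR3-AS1 (2.21-fold) and the multicopy RNA RN7SL1 (2.51-fold; adjusted p = 0.00141, and 0.0674 with DESeq2) are uncertain for the same reason. CDH1 rose 1.82-fold (log2 0.87, SE 0.099, adjusted p = 4.9e-07), while ID1 was 1.4-fold lower (adjusted p = 1.37e-06) and CYP1A1 2.25-fold lower (adjusted p = 0.001). ZEB1 had a log2 change of 0.14 (SE 0.078, adjusted p = 0.234, and 0.011 without SW620_DMSO replicate 3) and VIM one of -0.10 (SE 0.042, adjusted p = 0.0899, and 0.0229 with library totals alone) at 255 ± 4.5 and 237 ± 4.4 CPM (SD, n = 3). SMAD7 had one of -0.37 (SE 0.12, adjusted p = 0.0293), which was lost without SW620_DMSO replicate 1 (adjusted p = 0.137), SW620_RepSox replicate 1 (0.0747) or replicate 2 (0.124), and with DESeq2 (0.0751).

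Mesenchymal genes rose in SW620 in 11 of 27 and fell in 5 (12 and 6 adjusted over the list alone, camera adjusted p = 9.39e-10, and adjusted p = 0.0384 with an estimated correlation). Beside TAGLN, the collagen gene COL6A1 rose 1.95-fold and the myosin light chain MYL9 2.09-fold. Fibroblast markers, several of which are also in the mesenchymal list, went the other way, lower in 3 of 5 (3 adjusted over the list alone, camera adjusted p = 0.0487, and adjusted p = 0.172 with an estimated correlation). LUM, a member of both lists, was 1.82-fold lower. The ERK output list rose in 11 of 22 and fell in 3 (12 and 3 adjusted over the list alone, camera adjusted p = 1.96e-09, and adjusted p = 0.0384 with an estimated correlation), with the growth factor EREG 2.39-fold, EMP1 1.98-fold and the phosphatase DUSP4 1.7-fold higher and EGR1 lower. TGF-β target genes rose in 12 of 31 and fell in 7 (14 and 9 adjusted over the list alone, camera adjusted p = 2.79e-06, and adjusted p = 0.0787 with an estimated correlation), with TGFBI 1.97-fold, PMEPA1 1.84-fold and PDGFB 1.73-fold higher. NF-κB and cytokine genes rose in 7 of 18 and fell in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.000762, and adjusted p = 0.0787 with an estimated correlation), with the chemokine CXCL3 3-fold higher. Interferon genes fell in 11 of 22 and rose in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 0.000905, and adjusted p = 0.0787 with an estimated correlation). The NRF2 targets fell in 12 of 20 and rose in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 4.22e-05, and adjusted p = 0.0787 with an estimated correlation). Mitochondrially encoded mRNAs rose in 12 of 13 (13 adjusted over the list alone, camera adjusted p = 2.01e-06, and adjusted p = 0.26 with an estimated correlation). Epithelial genes had 9 higher and 7 lower of 39 (10 and 9 adjusted over the list alone, camera adjusted p = 0.155), with a median of -0.03 although the test's direction was up. KRT19 was 1.73-fold and KRT8 1.51-fold higher. WNT and stem cell genes had 9 higher and 9 lower of 20 (9 and 9 adjusted over the list alone, camera adjusted p = 0.833). The WNT inhibitor gene NKD1 went from 4400 ± 81 to 3090 ± 67 CPM (SD, n = 3).

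In SW620, edgeR's quasi-likelihood test called 3338 of 17147 genes (19.5%), 1754 higher and 1584 lower, and 302 changed at least 2-fold. The share of higher calls was 52.5% and became 39.5% when libraries were scaled by their totals alone, and a fit of all 18 libraries called 2019.

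The difference between the lines was tested as the RepSox effect in SW620 minus that in HT-29 iZEB1 without DOX. It was -4.57 on the log2 scale for MRAS (SE 0.22, adjusted p = 8.32e-13), which rose with RepSox in HT-29 iZEB1 without DOX and stood at 1.95 ± 0.075 and 1.51 ± 0.25 CPM (SD, n = 3) without and with RepSox in SW620. ANKRD22 (3.07, SE 0.19), SCEL (3.24, SE 0.31) and PRDM1, a transcriptional repressor gene (2.86, SE 0.47), had positive differences, and ARG2, which encodes an arginase (-2.58, SE 0.16), and FCGBP (-2.56, SE 0.46) negative ones. CDH1 differed by 1.15 (SE 0.11, adjusted p = 5.09e-08), ID1 by 0.85 (SE 0.12, adjusted p = 2.91e-05) and ZEB1 by 0.80 (SE 0.15, adjusted p = 0.000469). SMAD7 (0.11, SE 0.15, adjusted p = 0.714), VIM (0.19, SE 0.42, adjusted p = 0.867) and CYP1A1 (1.94, SE 0.81, adjusted p = 0.124) did not pass. ARHGAP40, CALB1, NINL, FERMT2, TMEM30B, GAL, ZNF311, EGR3, PNPLA3 and ADAMTS15 were called too. Each had a mean of at most 3 counts in at least 1 of the compared groups, and they are given no fold. Of these, FERMT2 lost its call without any 1 of the 12 libraries compared (adjusted p from 0.0539 to 0.137), EGR3 without 9 of them (from 0.0501 to 0.101) and TMEM30B without SW620_RepSox replicate 2 (0.105).

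Of 32 tested TGF-β target genes, 12 had a higher RepSox effect in SW620 and 1 a lower one (12 and 3 adjusted over the list alone, camera adjusted p = 5.08e-10, and adjusted p = 0.00692 with an estimated correlation). TAGLN differed by 2.64, NEDD9 by 1.78, PDGFB by 1.43 and TGFBI by 1.26 on the log2 scale. The ERK output list was higher in 12 of 22 and lower in 2 (13 and 2 adjusted over the list alone, camera adjusted p = 2.12e-08, and adjusted p = 0.00586 with an estimated correlation), with EMP1 at 2.01 and EREG at 1.02. Mesenchymal genes were higher in 6 of 30 and lower in 1 (8 and 2 adjusted over the list alone, camera adjusted p = 6.36e-05, and adjusted p = 0.0177 with an estimated correlation), with AXL at 0.83. YAP/TAZ targets were higher in 5 of 19 and lower in 2 (5 and 2 adjusted over the list alone, camera adjusted p = 0.00498, and adjusted p = 0.03 with an estimated correlation), with MYOF at 1.45. By edgeR's quasi-likelihood test 1982 of 19107 genes differed between the lines, 1029 higher and 953 lower in SW620, 337 by at least 2-fold. The higher share was 51.9%, 46.2% when libraries were scaled by their totals alone and 59.9% with RLE scaling. Of genes called in both lines, 1004 moved the same way and 311 opposite ways among 15160 tested in both (r = 0.21 across genes, which are not independent replicates, and the lines share no library). Higher in both were 447 and lower in both 557, against 202 and 191 for independent lists. Of the opposite moves, 82 rose in HT-29 iZEB1 and fell in SW620 and 229 did the reverse, against 189 and 204.

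**Figure D5:**
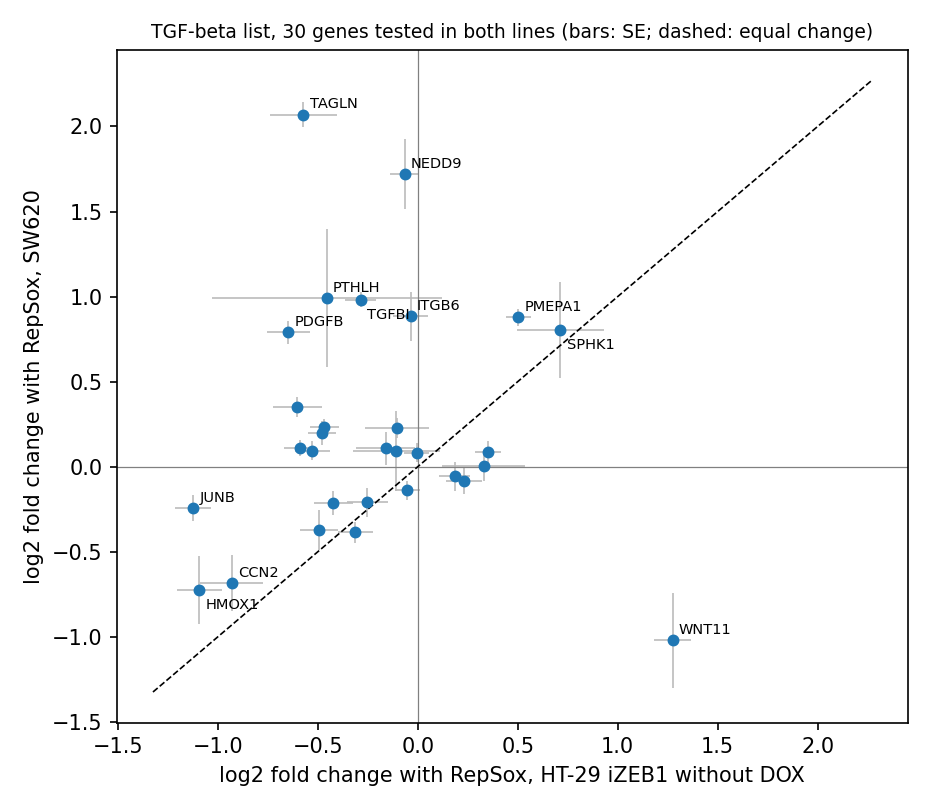
Log2 fold change with RepSox in HT-29 iZEB1 without DOX (horizontal axis) against SW620 (vertical axis) for 30 TGF-β list genes tested in both fits, with bars of 1 SE and a dashed line of equal change. TAGLN, at 2.07 in SW620, lies far above the line.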

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

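The results below were flagged because a test of the difference itself showed that the same contrast differed between groups. Of the tests weighed here, the confidence bound of ZEB1, the share of mixed material, the S-phase genes and the use of the SD between the RNAs without poly(A) tails, in place of a minimum of 5 such RNAs, were chosen only after the result was seen. The predictions of the others were fixed before their values were computed. The reasons for which the scaling test and the splits are given below as unsettled were not part of those predictions.

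The effect of RepSox differed with and without DOX in HT-29 iZEB1 for 3834 genes by the interaction term of edgeR. Among named genes the interaction was -3.90 on the log2 scale for ZEB1, 0.88 for CDH1 and -0.69 for SMAD7. It was positive for MAB21L4 (4.52), PLA2G4F (4.49), BICDL2 (3.60), TMPRSS4 (3.56), FGF19 (3.53), TMEM30B (3.38), MUC20P1 (3.32) and C1orf210 (3.19), and negative for ANGPTL2 (-4.44), SYNPO (-3.22), DOCK11 (-3.15), EMP3 (-3.03), HEG1 (-3.00), NAV3 (-2.71) and MAP1A (-2.70). The effect of RepSox differed between SW620 and HT-29 iZEB1 without DOX for 1982 genes, again by the interaction term. Among named genes the difference was 0.80 for ZEB1, 1.15 for CDH1, 0.85 for ID1, 3.24 for SCEL, 3.07 for ANKRD22, 2.86 for PRDM1, -4.57 for MRAS, -2.58 for ARG2 and -2.56 for FCGBP.

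The first pattern weighed is that ZEB1 and the changes seen with DOX were far smaller in cells that also had RepSox. If the libraries labelled DOX and RepSox came from cells without DOX, ZEB1 would not differ from RepSox alone, but the lower 95% bound of its log2 change was 1.35, which argues against that. If 2.84% of induced material had been mixed into uninduced RepSox libraries, the share that ZEB1 allows, the 6852 genes called with DOX in DMSO, ZEB1 left out, would have moved under RepSox by a median of 0.016 in their DMSO direction. They moved by 0.07, 4.39 times as much, and 3.75 to 5.03 times as much with each RepSox library left out in turn, which argues against mixing as the whole cause. The treatment itself, a biological reading that the design offers, stays open beside a lower effective dose or time of DOX, and the counts do not separate the inducible ZEB1 from the cells' own.

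The second pattern is that the TGF-β list moved up with RepSox in SW620 relative to HT-29 iZEB1. The list median of 0.29 became 0.32 with RLE scaling and 0.28 with library totals alone, and the list passed camera with both (adjusted p = 2.45e-10 and 5.17e-10). These scalings moved all genes by a median of only 0.025 and -0.017, so they test the size of the median weakly. Camera sets the list against the other genes, and scaling moves all genes of a library alike. The calls under both scalings were therefore largely fixed in advance, and they do not test scaling between libraries as a cause. If members near the detection floor were the cause, the 19 of 32 members with at least 5 CPM in each line would not show it, and their median was 0.26 and still passed camera. This argues against the detection floor, and a difference between the lines stays open. Scaling between libraries was not settled by these values and stays open as to the size of the list median.

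The third pattern is that replication-dependent histone genes were higher with DOX in DMSO, with a list median of 0.83. This list call did not hold with an estimated correlation. If RNA without poly(A) tails had leaked into the DOX libraries, other such RNAs would rise by at least 0.42 as a set. Of 25 listed, 4 had counts enough for a test, RMRP, SNORA73B, SNORD3A and SNORD17, and their median was -0.57 (SD 0.56 between them, from -0.84 to 0.38). These 4 RNAs did not rise as a set. They are fewer than the minimum given above and have low counts, so they do not settle whether leakage played a part. If more cells were in S phase, S-phase genes would not fall, and 17 of 17 did, with a median of -0.94, which argues against it. Leakage stays open, and so does an effect of the DOX treatment on these genes by another route, which was not tested.

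The counts of calls were set beside other ways of splitting the libraries between the compared groups. Each comparison of 2 groups has 10 splits, the real one included, and in each only the real one (1) reached its own count: 6853, 8864 and 4290 against 0 in any other split for DOX in DMSO, RepSox with DOX and RepSox without DOX, 81 against at most 1 for DOX in RepSox, and 3338 against 0 for RepSox in SW620. With 10 splits no share under 0.05 can be reached, so these counts cannot settle whether chance grouped the libraries. For the interaction 7 of 100 splits drawn reached 3834, the highest other calling 8793. In the 6 other splits the labels with DOX were left as they were and most or all of those without DOX were exchanged, so that the term came closer to the sum of both RepSox effects than to their difference. These splits therefore do not settle whether chance grouped the libraries. For the difference between the lines 2 of 100 splits reached 1982, the other one calling 4354 with the labels of HT-29 iZEB1 fully exchanged. The next highest called 1947, with the labels of HT-29 iZEB1 kept and those of SW620 mixed, so here too the splits carry a RepSox effect and do not settle whether chance grouped the libraries. In both cases 25 of the other splits kept or exchanged the labels of a whole pair of groups, and the 74 that mixed both pairs called 0. Under the prediction fixed beforehand, a share under 0.05 counts against chance. The interaction missed that share and the difference between the lines met it, before the make-up of the splits was considered.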

How the results depend on the processing

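No named gene or list called in either setting reversed its direction between the main setting and an alternative it was checked under. The directions of other genes were not compared between settings. All alternatives were fixed before the data were examined. For the interaction, the interferon and ERK output lists, called by neither test, pointed down with camera and up with fry. With library totals alone the share of higher calls went from 47.6% to 59.5% for DOX in DMSO, from 51.3% to 43.7% for RepSox with DOX, from 57.4% to 47% for the interaction, from 52.5% to 39.5% for SW620 and from 51.9% to 46.2% for the difference between the lines, where RLE scaling gave 59.9%, so the majority direction of these calls depends on the scaling. Requiring at least a 2-fold change left 1350 calls for DOX in DMSO, 1967 for RepSox with DOX, 444 for RepSox without DOX, 8 for DOX in RepSox, 894 for the interaction, 302 for SW620 and 337 for the difference between the lines; the alternative itself asks for larger changes. For DOX in RepSox the count of 81 became 264 with DESeq2, 584 with no low-count filter, 162 in 1 fit of all 18 libraries and 27 to 1670 when libraries were left out in turn, and the cause was not tested. The SW620 count of 3338 became 2019 in 1 fit of all 18 libraries, where the cause was not tested. Leaving out libraries in turn gave 5812 to 7055 calls for DOX in DMSO, 7869 to 8730 for RepSox with DOX, 3207 to 3591 for RepSox without DOX, 3221 to 4393 for the interaction, 2359 to 4043 for SW620 and 1521 to 1844 for the difference between the lines. Of 78 list calls, 12 held with an estimated correlation and 66 did not. That test is stricter for lists whose genes vary together. Replicates share only a number: same-number libraries correlated between -0.14 and 0.10, and the number as a block gave 6955, 8948, 4446, 109, 3925, 2848 and 1855 calls in the order above, and 5546 opposite moves in place of 5479. Of the results of named genes, 570 stayed on the same side of the threshold with DESeq2, 11 lost their call and 1 gained it. With library totals alone 591 stayed, 2 lost it and 1 gained it, and with RLE scaling 592 stayed and 2 lost it. With the replicate number as a block 588 stayed and 6 lost it. Over all omissions of 1 library, counted once for each gene and library, 4436 stayed, 199 lost it and 3 gained it. The largest median shift between scalings was 0.075 on the log2 scale. Small changes were the most limited in the simulations: at the smallest fold 28% were recovered for DOX in DMSO and 2% for the difference between the lines. Far fewer genes changed there than were called in the data, so these shares do not carry over to it.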

Other observations

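Further members of the WNT, aryl hydrocarbon receptor and intestinal lists changed as follows. MYC rose with RepSox in HT-29 iZEB1 without DOX, 1.92-fold (log2 0.94, SE 0.065, adjusted p = 1.24e-08, n = 3 in each group), and with DOX, 3.02-fold (log2 1.60, SE 0.066, adjusted p = 1.22e-12). PROM1, a stem cell surface marker gene, rose 2.09-fold and 2.34-fold in the same comparisons and 1.66-fold in SW620. AXIN2 fell with RepSox, 1.65-fold without and 3.75-fold with DOX. The aldehyde dehydrogenase gene ALDH3A1 stood at 39 CPM with DMSO alone, 125 CPM with DOX and DMSO, 18.3 CPM with RepSox alone and 19.4 CPM with both (means of 3 libraries). KRT20, an enterocyte keratin gene, was 2.43-fold lower with RepSox without DOX.

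The share of counts from mitochondrially encoded genes was also taken, without limiting it to the listed mRNAs. In HT-29 iZEB1 it was 4.84 ± 0.5% with DMSO alone and 3.54 ± 0.9% with RepSox alone (SD, n = 3). It was 4.41 ± 1.4% with DOX and DMSO and 3.33 ± 0.46% with DOX and RepSox (SD, n = 3). In SW620 it was 4.9 ± 0.25% in DMSO and 5.5 ± 0.51% in RepSox (SD, n = 3).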
